A study of Mus musculus with 36 samples.

How the data were processed

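Brain samples of APP/PS1 mice, which carry APP695swe and PS1-dE9 transgenes, and of wild-type C57BL/6 mice were compared at 6 and 9 months of age. The 36 samples were 3 kinds of library (circRNA, long RNA and small RNA) in 4 groups of genotype and age, with 3 libraries in each group. The long RNA libraries gave an mRNA table and a lncRNA table. Groups and library numbers were taken from the titles and characteristics in the labels. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, frozen tissue was extracted with Trizol and 1 µg of total RNA went into an Illumina TruSeq RNA kit. The same protocol text names retinas as the tissue removed, while the tissue label of every sample reads brain, and no source used here resolves this.

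The circRNA and miRNA tables hold whole-number read counts per feature and a second set of columns scaled to a common total, which the authors deposited side by side under the name TPM. The deposited miRNA values named TPM equalled the count divided by the library's total and scaled to a common total, with no length term, so they are written here as CPM. The deposited mRNA and lncRNA tables hold FPKM per transcript, made by the authors, and no counts, so the depth of the long RNA libraries is unknown. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm8 were used, with no role stated. The counting tools, the circRNA caller and the annotation are not given in the sources used here. The deposited circRNA counts were 0 or at least 2 in every library, and no value of 1 occurred. A circRNA listed at 0 may therefore have been below a minimum, and no upper limit or bound on a fold was taken from such zeros.

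Transcript FPKM were summed per gene, giving 22154 genes from 48717 transcripts in the mRNA table and 2133 from 2462 in the lncRNA table. Of their gene IDs, 98.1% and 98.2% matched a reference table of mouse gene names, and no coordinates were used. The circRNA table does not pair its IDs with gene names, so circRNAs are given by ID. Genes with a mean of at least 0.5 FPKM over the 12 libraries entered the tests (13593 mRNA and 1367 lncRNA genes). Values were analysed as log2(FPKM + 0.25) with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) in R 4.3.3. A log2 change is on that scale and understates the change of genes with low values. The plan had foreseen edgeR for the lncRNA table. As that table holds FPKM only, limma was used in its place.

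CircRNA and miRNA counts were tested with the quasi-likelihood F test of edgeR 4.0.16 with TMM scaling. An SE given with these edgeR results is the size of the log2 change divided by the square root of F, so it restates the test. CircRNAs needed at least 2 reads in at least 3 libraries and 20 reads in all (14872 tested), and miRNAs passed filterByExpr (560 tested). For every kind of RNA the 12 libraries entered a single model with 4 group means, so that all groups shared an estimate of the spread. The contrasts were APP/PS1 against wild type at 6 months, the same at 9 months, 9 against 6 months over both genotypes, and the difference of the genotype effect between the ages. For mRNA the genotype effect over both ages was added. Benjamini-Hochberg adjusted p-values under 0.05 were called, and all tests were two-sided.

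Gene lists for brain cell types, brain regions, pathways and miRNA groups were fixed before the data were examined, as were the tests and the rule for named genes. There were 34 lists for mRNA and 9 for miRNA. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the data. Named features were at most 12 per direction by log2 change among those called, with a mean of at least 1 FPKM or 10 reads and, for genotype at a given age, no overlap between the groups. App and Prnp were always named (another gene of that rule is not reported here), as were up to 6 list members per list with an adjusted p under 0.05 over all genes or over the list alone. With fewer than 5 calls, the 5 features of smallest p were given without being called changed.

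The circRNA totals ran from 247998 to 654147 reads per library and the miRNA totals from 5082755 to 8595108. Counting error at these depths does not cover duplicates from amplification, since molecules were not tagged. The tests were run on simulated data before use, with 67, 67 and 66 features of each kind changed 1.5-fold, 2-fold and 4-fold in the comparison of genotypes at 9 months. Among 13553 simulated mRNA genes, 62.7% of 1.5-fold, 92.5% of 2-fold and 95.5% of 4-fold changes were called, and 1.76% of the calls were unchanged genes. For 1311 lncRNA genes the shares were 43.3%, 77.6% and 80.3%, and for 550 miRNAs 38.8%, 76.1% and 97.0%. For 14408 circRNAs they were 0%, 1.49% and 33.3%, so changes of 2-fold or less in a circRNA were rarely detectable. In the simulated list test, a complement list raised by 0.5 log2 was called (camera adjusted p = 7.81e-14) and 0 of 33 other lists were. Genes were drawn independently there, so the simulation does not show how often correlated lists are called without a change. In the data the estimated correlation was 0.837 for choroid plexus genes. Other groupings of the libraries called a median of 6 to 8 mRNA lists at the preset correlation, though such groupings can keep a part of the real contrast.

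Results were recomputed with other pseudocounts, no filter or another filter, median-of-ratios or RLE scaling, the authors' depth, DESeq2 1.42.0 in place of edgeR, a fit of only the groups compared, the library number as a block, camera with an estimated correlation and leaving out each library in turn. Added after seeing the data were the most abundant transcript in place of the sum, region covariates, leaving out a pair of libraries with high olfactory bulb or pituitary markers, leaving out circRNAs that are absent in some libraries and well read in the others, the FPKM settings (pseudocounts and scaling) for the lncRNA table, and every alternative for the miRNA lists. Region covariates were the mean log2 levels of olfactory bulb and choroid plexus markers. The olfactory bulb markers were listed after the miRNA result was seen. Pairs of libraries were also compared for duplicates. Replicates correlated at 0.711 to 0.860 across circRNAs, 0.953 to 0.996 across miRNAs, 0.983 to 0.989 across mRNA genes and 0.932 to 0.961 across lncRNA genes, which are not independent replicates, and no pair of count libraries came as close as sampling noise.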

Results

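Deep sequencing of brain RNA was used to compare APP/PS1 mice with wild-type mice at 6 and 9 months of age. APP/PS1 mice carry transgenes that raise amyloid production and form amyloid plaques in the brain as they age. The design text asks how the whole transcriptome differs between the genotypes at both ages. Each of the 4 groups had 3 libraries of each kind. CircRNA libraries held 247998 to 654147 reads, the fewest in WT 2 at 9 months and the most in WT 1 at 9 months, and 12163 to 14447 of 15690 listed circRNAs were detected per library. Small RNA libraries held 5082755 to 8595108 miRNA reads with 910 to 1008 of 1411 miRNAs detected. The FPKM of the mRNA genes summed to 292540 to 301778 per library, with 16757 to 17062 genes above 0. In the lncRNA table the sums were 18747.5 to 24221.3, and 10 genes held 84.1% to 87.7% of them. Values below are means ± SD with n = 3 libraries per group.

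The genotype labels were checked in the 12 long RNA libraries, by App and Prnp. App lay at 435.7, 440.7 and 433.3 FPKM in the wild-type libraries of 6 months and at 969.9, 971.1 and 1006.8 in the APP/PS1 libraries. At 9 months it lay at 453.0, 443.7 and 447.8 in wild type and at 1029.2, 973.2 and 1004.2 in APP/PS1. Prnp, the gene of the prion protein whose promoter drives the transgenes, lay at 253.6, 248.8 and 255.9 in wild type and at 717.6, 726.7 and 739.3 in APP/PS1 at 6 months. Its values at 9 months were 265.4, 269.0 and 253.1 in wild type and 759.6, 744.2 and 732.1 in APP/PS1. No long RNA library went against its genotype label, and the labels of the circRNA and small RNA libraries were not tested. These FPKM do not tell reads of the mouse genes App and Prnp from reads of sequence carried by the transgenes.

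**Figure D1:**
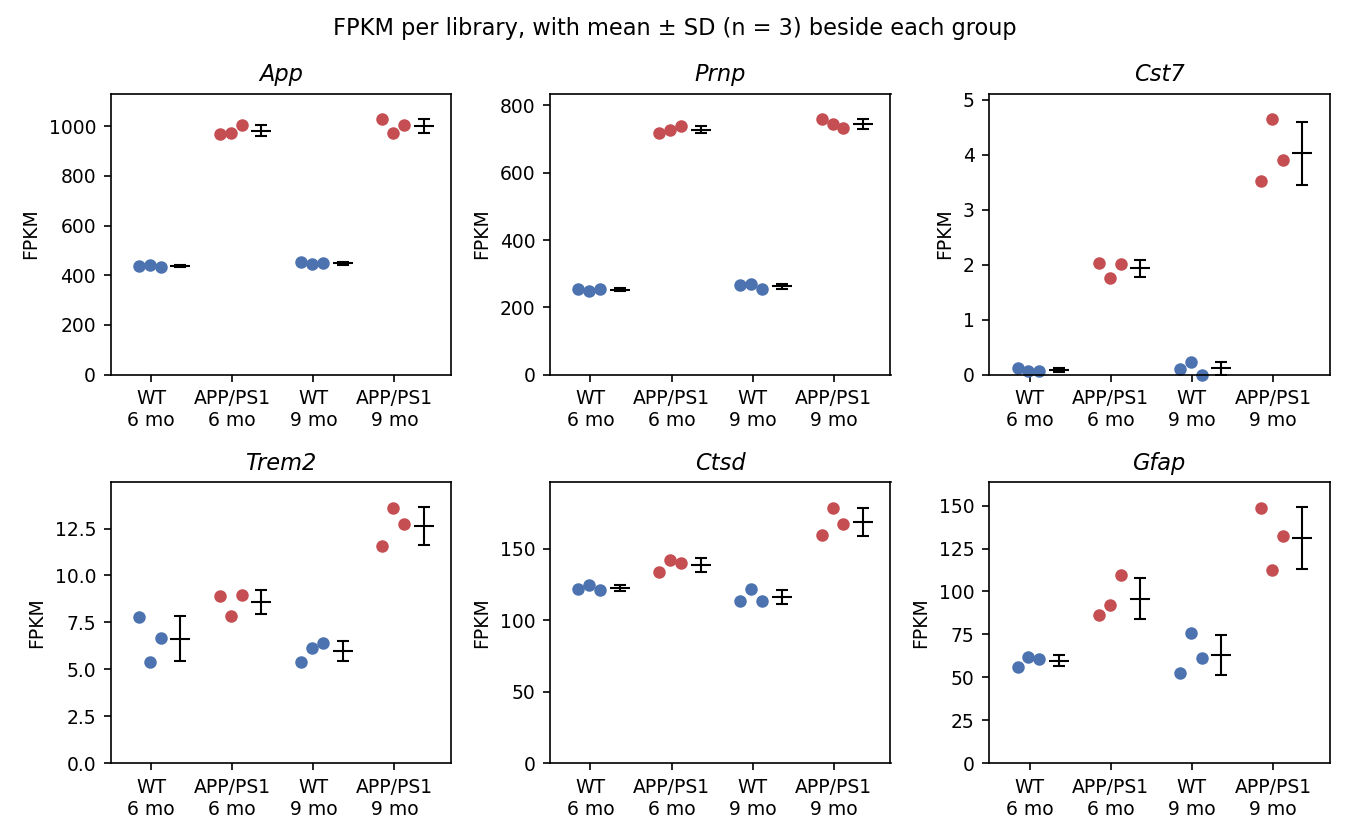
FPKM per library for App, Prnp, Cst7, Trem2, Ctsd and Gfap in wild-type (blue) and APP/PS1 (red) brain at 6 and 9 months, with the mean ± SD (n = 3) in black beside each group. App and Prnp separate the genotypes at both ages, and Cst7 reaches 1.93 ± 0.155 at 6 months and 4.02 ± 0.573 at 9 months in APP/PS1.

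At 6 months the clearest change outside the transgene was in Cst7, the gene of cystatin F, a protease inhibitor of activated microglia. Cst7 rose from 0.0852 ± 0.0366 FPKM in wild type to 1.93 ± 0.155 in APP/PS1 (log2 2.71, SE 0.21, limma adjusted p = 0.000278). Prnp rose from 253 ± 3.60 to 728 ± 10.9 FPKM (log2 1.52, SE 0.04, adjusted p = 4.53e-09) and App from 437 ± 3.79 to 983 ± 20.98 (log2 1.17, SE 0.04, adjusted p = 5.93e-08). Fahd1, a mitochondrial hydrolase gene, rose by 0.53 log2 (5.54 ± 0.390 to 8.08 ± 0.394, adjusted p = 0.0471). The pseudogene model Gm5900 fell by 1.84 log2 (2.72 ± 0.218 to 0.608 ± 0.254, adjusted p = 0.0167), and Gapdh, the glycolytic enzyme gene, rose by 1.42 log2 (3.89 ± 0.757 to 10.8 ± 1.41, adjusted p = 0.0112). Both are uncertain, because near-identical copies can share their reads. In each of these 6 genes the 3 APP/PS1 libraries lay beyond all 3 wild-type libraries. In all, 6 of 13593 genes were called, 5 higher and 1 lower, while 1596 had an unadjusted p under 0.05 against 679.7 by chance, and the groups did not overlap in 15.8% of genes (10% by chance). Gapdh was no longer called without APP/PS1 2 of 6 months (adjusted p = 0.0703), nor Gm5900 without WT 1, 2 or 3 of 6 months (0.0617, 0.0696 and 0.0575). Fahd1 kept its call only without WT 3 or APP/PS1 3 of 9 months or APP/PS1 3 of 6 months, with adjusted p up to 0.237 without APP/PS1 2 of 6 months. With region covariates Gapdh, Gm5900 and Fahd1 lost their calls (adjusted p = 0.0681, 0.0776 and 0.251), App, Prnp and Cst7 kept theirs, and 4 other genes were called. The count reached 12 without APP/PS1 1 and 17 without APP/PS1 3 of 6 months, and was 4 without APP/PS1 2 of that age.

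Genes of disease-associated microglia, the state that microglia take on near plaques, were higher as a list at 6 months (14 of 19 measured members higher, median log2 0.10, camera adjusted p = 0.000171). The call was lost with the correlation estimated (adjusted p = 0.202 with an estimated correlation). Adjusted over the list alone 6 members rose, and over all genes 1, Cst7. Ctsz, a cathepsin gene, was among the 6 (15.2 ± 0.398 to 19.0 ± 1.82 FPKM, log2 0.32), as was Tyrobp, the adaptor of Trem2 (10.7 ± 2.47 to 16.1 ± 1.27, log2 0.61), whose call over the list ended without 1 of the libraries (adjusted p up to 0.0561). Homeostatic microglial genes were higher in 10 of 12 (median 0.15, adjusted p = 0.00511, and 0.474 with an estimated correlation), with 0 members past the threshold over the list alone or over all genes, and without WT 2 of 6 months the list was not called (0.065). The type I interferon genes were higher in 13 of 13 (median 0.30, adjusted p = 2.59e-06, and 0.214 with an estimated correlation). In that list 1 member, Bst2, rose adjusted over the list alone (1.90 ± 0.378 to 3.54 ± 1.11 FPKM, log2 0.78), which 8 of the 12 fits without a library did not call (adjusted p up to 0.156 without WT 3 of 6 months), and 0 rose over all genes. The amyloid precursor list was higher in 7 of 13 (median 0.04) and was called through its members App and Prnp (2 adjusted over the list alone and 2 over all genes, adjusted p = 0.00378, and 0.202 with an estimated correlation), and was not called without APP/PS1 1 of 6 months (0.076).

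Striatal genes were lower in 9 of 9 members in APP/PS1 at 6 months (median log2 −0.25, camera adjusted p = 1.52e-06, and adjusted p = 0.27 with an estimated correlation). Adjusted over the list alone 5 fell, and over all genes 0. Adora2a, an adenosine receptor gene of striatal neurons, fell from 16.01 ± 1.82 to 11.8 ± 0.762 FPKM (log2 −0.43), and Ppp1r1b, a phosphatase regulator of the same neurons, from 135 ± 11.6 to 110.2 ± 3.17 (log2 −0.29). Circadian clock genes were lower in 10 of 13 (median −0.14, adjusted p = 0.000725, and 0.27 with an estimated correlation), with 4 lower adjusted over the list alone and 0 over all genes. Dbp fell from 43.4 ± 3.22 to 33.0 ± 3.98 FPKM and Per2 from 10.4 ± 0.477 to 8.58 ± 0.468. Markers of other tissue differed in mean between the genotypes here, although single libraries overlapped. Choroid plexus genes were higher in 12 of 12 (median 1.02, adjusted p = 1.79e-05, and 0.474 with an estimated correlation), with mean log2 levels of −0.67, 1.93 and −0.11 in wild type and 0.79, 2.05 and 2.001 in APP/PS1. Ependymal cilia genes were higher in 6 of 7 (median 0.26, adjusted p = 0.0332, and 0.474 with an estimated correlation), a call lost without WT 1 (0.269), WT 3 (0.15) or APP/PS1 3 (0.21) of 6 months. Mitochondrially encoded genes were higher in 13 of 13 (median 0.33, adjusted p = 8.71e-05, and 0.474 with an estimated correlation). With region covariates the ependymal list was not called (adjusted p = 0.931), nor the amyloid list (0.0755).

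In the other lists at 6 months, at most 2 members each passed adjusted over the list alone and 0 passed over all genes. Gfap, the intermediate filament of reactive astrocytes, rose from 59.7 ± 3.12 to 95.9 ± 11.99 FPKM (log2 0.67, adjusted p = 0.00577 over the list alone and 0.131 over all genes). The reactive astrocyte list itself was not called (camera adjusted p = 0.472), and its mean was negative (−0.04) while its median and test were positive. Npas4, an activity-induced transcription factor of neurons, fell by 0.75 log2 (3.79 ± 0.244 to 2.20 ± 0.560), and Atf4, a stress-response factor, rose by 0.43 (34.1 ± 1.90 to 45.9 ± 2.29), both over their lists alone. Xbp1, of the same list as Atf4, fell by 0.31 (38.96 ± 4.48 to 31.4 ± 1.43, adjusted p = 0.0159 over the list alone), a call lost without WT 2 (0.0683), WT 3 (0.0818), APP/PS1 1 (0.0685) or APP/PS1 3 (0.0557) of 6 months.

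At 9 months genes of activated microglia and the astrocyte gene Gfap were higher in APP/PS1. Cst7 rose from 0.115 ± 0.118 to 4.02 ± 0.573 FPKM (log2 3.59, SE 0.21, limma adjusted p = 1.41e-05), and Ctsd, the gene of the lysosomal protease cathepsin D, from 116 ± 4.82 to 168 ± 9.80 (log2 0.54, SE 0.05, adjusted p = 0.000972). Trem2, the microglial lipid receptor, rose from 5.98 ± 0.517 to 12.6 ± 1.03 (log2 1.05, SE 0.12, adjusted p = 0.00622), Lyz2, a lysozyme gene of myeloid cells, from 4.11 ± 0.455 to 8.40 ± 1.04 (log2 0.98, adjusted p = 0.00991), and Gfap from 63.2 ± 11.6 to 131 ± 18.3 (log2 1.06, adjusted p = 0.0138). Fdft1, squalene synthase of the cholesterol pathway, rose from 24.0 ± 0.833 to 30.4 ± 0.846 (log2 0.34, adjusted p = 0.00622). Ctsz (log2 0.50, adjusted p = 0.0335), Plek, a pleckstrin gene of blood and myeloid cells (0.57, adjusted p = 0.0472), and Hdac1 (0.78, adjusted p = 0.0335) were also higher. Hdac1 is uncertain, since its likely copy Gm10093 moved the other way and their sum lay at 6.32 ± 0.363 in wild type and 7.52 ± 0.185 in APP/PS1. Egr1, an activity-induced transcription factor, fell from 57.7 ± 2.64 to 38.2 ± 3.19 (log2 −0.59, adjusted p = 0.0335) and Arpp21, a phosphoprotein of forebrain neurons, from 62.6 ± 3.42 to 45.1 ± 0.481 (log2 −0.47, adjusted p = 0.0335). With Prnp (log2 1.505, adjusted p = 5.24e-09) and App (1.16, adjusted p = 6.48e-08) these made 13 calls, 11 higher and 2 lower, each with the 3 APP/PS1 libraries beyond all 3 wild-type libraries. At an unadjusted p under 0.05 there were 1322 genes (679.7 by chance), and the groups did not overlap in 17.3% of genes (10% by chance).

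Leaving out single libraries ended some of the calls at 9 months. Trem2, Fdft1 and Lyz2 were not called without APP/PS1 3 of 9 months (limma adjusted p = 0.0501, 0.0506 and 0.052), and Gfap was not called without WT 1, WT 3, APP/PS1 1 or APP/PS1 3 of 9 months (0.0624, 0.0669, 0.0601 and 0.0914). Hdac1 was lost in 7 of the 12 fits, Egr1 and Arpp21 in 9, Ctsz in 10 and Plek in 11, with any library of 9 months among them except WT 3 for Plek and APP/PS1 2 for Egr1, and with adjusted p up to 0.213, 0.156, 0.213, 0.213 and 0.229 without WT 1. The count fell to 7 without WT 1 and to 5 without APP/PS1 3 of 9 months. Cst7, Ctsd, App and Prnp were called in every fit that left out a library. With region covariates these 4, Trem2 and Lyz2 kept their calls, the other 7 lost theirs (adjusted p from 0.051 for Fdft1 to 0.254 for Plek), and 1 other gene was called. The median log2 changes of all genes were 0.01 at 9 months and −0.01 at 6 months. Across genes, which are not independent replicates, the genotype changes at the ages had a Pearson r of 0.008 and a Spearman rho of −0.034.

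**Figure D2:**
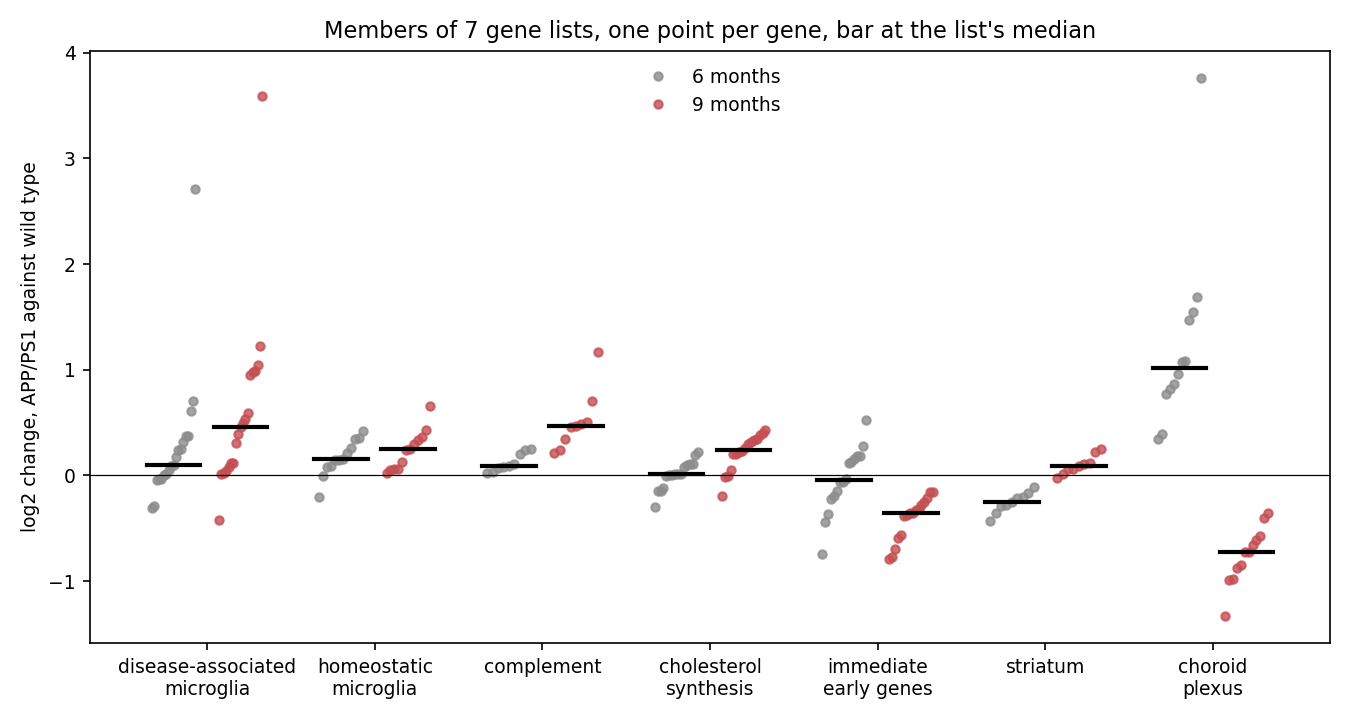
Log2 change of APP/PS1 against wild type at 6 months (grey) and 9 months (red) for the measured members of 7 gene lists, with a point per gene and a black bar at each list's median. Disease-associated microglial genes have medians of 0.10 and 0.46 at 6 and 9 months, immediate early genes lie below 0 for 16 of 16 members at 9 months, and choroid plexus genes lie above 0 at 6 months and below 0 at 9 months.

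The disease-associated microglial list was higher at 9 months in 18 of 19 members (median log2 0.46, camera adjusted p = 1.92e-16, and 0.00313 with an estimated correlation). Adjusted over the list alone 11 members rose, and over all genes 5. Tyrobp rose from 11.6 ± 1.33 to 22.6 ± 3.04 FPKM over the list alone (log2 0.95), while Apoe, the lipid carrier made by astrocytes and microglia, was the member below 0 and was not called (log2 −0.42). Complement genes were higher in 9 of 9 (median 0.47, adjusted p = 1.49e-09, and 0.0159 with an estimated correlation), with 8 higher adjusted over the list alone and 0 over all genes. Itgb2, a subunit of complement receptor, rose from 1.40 ± 0.141 to 2.09 ± 0.0632 FPKM, and C4b from 5.70 ± 1.31 to 12.99 ± 2.32, although C4b can share reads with its near copy. Homeostatic microglial genes were higher in 12 of 12 (median 0.25, adjusted p = 1.94e-05, and 0.229 with an estimated correlation). Of these, 5 rose adjusted over the list alone and 0 over all genes, with Gpr34, a microglial receptor gene, going from 3.67 ± 0.303 to 6.003 ± 1.07 FPKM. Interferon genes were higher in 12 of 13 (median 0.28, adjusted p = 0.00137, and 0.271 with an estimated correlation) and antigen presentation genes in 13 of 13 (median 0.28, adjusted p = 0.00746, and 0.11 with an estimated correlation). The interferon list had 1 member higher adjusted over the list alone and 0 over all genes, and antigen presentation 0 and 0. Neither was called without a library of APP/PS1 at 9 months, APP/PS1 2 for interferon (0.0653) and APP/PS1 3 for antigen presentation (0.0538).

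Cholesterol synthesis genes were higher in 13 of 16 members at 9 months (median log2 0.24, camera adjusted p = 4.44e-12, and 0.0321 with an estimated correlation). Adjusted over the list alone 12 rose, and over all genes 1, Fdft1. Fdps, which makes farnesyl diphosphate, rose from 28.2 ± 2.11 to 35.2 ± 1.08 FPKM over the list alone, and Lss, lanosterol synthase, from 5.38 ± 0.254 to 7.11 ± 0.458. Immediate early genes, which neuronal activity induces within minutes, were lower in 16 of 16 (median −0.35, adjusted p = 1.12e-16, and 0.0507 with an estimated correlation). Of these, 12 fell adjusted over the list alone and 1, Egr1, over all genes. Arc fell from 87.2 ± 6.85 to 51.2 ± 6.03 FPKM (log2 −0.77), Fos from 11.1 ± 1.45 to 6.35 ± 0.837 (log2 −0.79) and Nr4a1 from 35.7 ± 1.49 to 24.2 ± 2.79 (log2 −0.56), each over the list alone. Protein folding stress genes were lower in 11 of 11 (median −0.25, adjusted p = 4.28e-09, and 0.125 with an estimated correlation), with 7 lower adjusted over the list alone and 0 over all genes. Hspa5, the chaperone BiP of the endoplasmic reticulum, went from 131 ± 14.5 to 97.4 ± 7.11 FPKM, and its call over the list was lost in 4 of the 12 fits that left out a library (adjusted p up to 0.1). The reactive astrocyte list was not called at 9 months (8 of 14 higher, median 0.02, mean −0.11, adjusted p = 0.76), with 2 members higher, Gfap and Aspg, and 1 lower, Hspb1, adjusted over the list alone. Aspg was lost without any library of 9 months but WT 2 (adjusted p up to 0.129 without APP/PS1 3) and Hspb1 without any but WT 3 (up to 0.108 without WT 1).

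Region and tissue lists were called for genotype at 9 months too, with choroid plexus, ependymal and striatal genes opposite in direction to 6 months. Choroid plexus genes were lower in 12 of 12 in APP/PS1 (median log2 −0.72, camera adjusted p = 0.00145, and 0.594 with an estimated correlation), with mean log2 levels of 1.82, 2.01 and 2.07 in wild type and 1.08, 0.75 and 1.81 in APP/PS1. Ependymal cilia genes were lower in 6 of 7 (median −0.43, adjusted p = 0.00801, and 0.302 with an estimated correlation), 2 of them adjusted over the list alone. Pituitary genes were higher in 3 of 3 (median 1.62, adjusted p = 0.0372, and 0.271 with an estimated correlation), with the highest level in APP/PS1 1, and were not called without WT 1 (0.11), WT 3 (0.132) or APP/PS1 1 (0.0816) of 9 months. Striatal genes were higher in 8 of 9 (median 0.09, adjusted p = 0.0301, and 0.594 with an estimated correlation), a call lost without WT 3 (0.151), APP/PS1 2 (0.233) or APP/PS1 3 (0.229) of 9 months. Oligodendrocyte genes were higher in 12 of 12 (median 0.14, adjusted p = 0.00683, and 0.594 with an estimated correlation), but not called without WT 1 (0.483) or APP/PS1 3 (0.0538) of 9 months. Adjusted p-values of 0.0402 to 0.0483 were reached by lower oxidative phosphorylation genes (17 of 22), glutamatergic synapse genes (10 of 13), blood cell genes (7 of 7) and circadian genes (9 of 13), with 0.661, 0.594, 0.454 and 0.499 as adjusted p with an estimated correlation. Each of these 4 lists was lost in 4 to 9 of the 12 fits without a library, among them those without APP/PS1 3 of 9 months for the others (0.438, 0.264 and 0.194) and APP/PS1 2 for circadian genes (0.223). With region covariates the ependymal, blood, striatum, pituitary, oligodendrocyte and circadian lists were not called, with adjusted p from 0.0664 to 0.256.

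Over both ages 16 genes differed between the genotypes, 12 higher and 4 lower in APP/PS1. Beside Prnp (log2 1.51, limma adjusted p = 1.09e-10), App (1.17, 1.41e-09) and Cst7 (3.15, 1.41e-06), Ctsd rose by 0.36 (adjusted p = 0.00178), Gfap by 0.87 (0.00453), Trem2 by 0.71 (0.00784), Ctsz by 0.41 (0.0121) and Tyrobp by 0.78 (0.0299). Arpp21 fell by 0.44 (0.00453). In all of these genes the 6 APP/PS1 libraries lay beyond the 6 wild-type libraries, where 0.736% of all genes did so. Stard4, a sterol transporter gene (log2 0.39, adjusted p = 0.0352), Fdft1 (0.18), Tfrc, the transferrin receptor gene (0.37), and Plek (0.39) were higher, and Gm5900 (−1.05), Hist1h2ao (−0.34) and Ccdc64 (−0.32) lower, at an adjusted p of 0.0497 except Stard4. Hist1h2ao belongs to a family of near-identical histone genes and is uncertain. These 7 were lost in 9 to 12 of the 12 fits that left out a library, with adjusted p up to 0.139 without WT 1 of 9 months, and Tyrobp in 8 (up to 0.0789 without the same library). Of these 7, all but Gm5900 were also lost with region covariates (adjusted p from 0.0533 to 0.12). At an unadjusted p under 0.05 there were 1416 genes, against 679.7 by chance. The count was 9 without WT 3 of 6 months, 8 without WT 1 of 9 months and 10 without WT 2 or APP/PS1 2 of 6 months or APP/PS1 2 or 3 of 9 months.

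Over both ages the disease-associated microglial list (16 of 19 higher, median log2 0.36, camera adjusted p = 5.4e-15) and the complement list (9 of 9, 0.27, adjusted p = 1.38e-08) held with an estimated correlation (adjusted p = 0.00406 and 0.0234 with an estimated correlation). Adjusted over the list alone 12 and 7 of their members rose, and 5 and 0 over all genes. Immediate early genes were lower in 16 of 16 (median −0.19, camera adjusted p = 1.97e-10, and 0.0862 with an estimated correlation). Of these, 9 were lower adjusted over the list alone and 0 over all genes. At 6 months alone that list was not called (7 higher and 9 lower, median −0.04, camera adjusted p = 0.658). Jun fell by 0.23 and Egr4 by 0.30 over that list. Cholesterol synthesis genes were higher in 14 of 16 (median 0.16, adjusted p = 2.47e-09, and 0.0513 with an estimated correlation), with 10 adjusted over the list alone and 1 over all genes, and interferon genes in 13 of 13 (0.27, 8.91e-09, and 0.0627 with an estimated correlation), with 7 and 0. Sqle, squalene epoxidase, rose by 0.23 and Ifit3, an interferon-induced gene, by 0.41 over those lists. Homeostatic microglial genes (median 0.25, adjusted p = 1.01e-06) and protein folding genes (−0.24, adjusted p = 7.38e-06) had 7 higher and 6 lower adjusted over the list alone and 0 over all genes, and adjusted p = 0.132 and 0.205 with an estimated correlation. Circadian genes (−0.08, adjusted p = 2.77e-05), the amyloid list (0.02, 0.000469) and antigen presentation (0.20, 0.00292) had 0.0862, 0.0513 and 0.0713 as adjusted p with an estimated correlation. Mitochondrially encoded genes (0.15, 0.00871), blood cell genes (−0.23, 0.0125), striatal genes (−0.10, 0.0125), pituitary genes (1.504, 0.0125) and oligodendrocyte genes (0.07, 0.0135) were called at the preset correlation, with 0.624, 0.284, 0.624, 0.165 and 0.743 as adjusted p with an estimated correlation. Of these 5, only the pituitary list was called in every fit without a library. The others were lost at up to 0.192 without APP/PS1 3 of 6 months (mitochondrial), 0.0556 without APP/PS1 3 of 9 months (blood), 0.194 without APP/PS1 1 of 9 months (striatum) and 0.439 without WT 1 of 9 months (oligodendrocyte).

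With age, over both genotypes, 2 of 13593 mRNA genes were called, both higher at 9 months. Pglyrp1, an innate immune gene for a peptidoglycan-binding protein, rose from 3.15 and 3.77 FPKM in wild type and APP/PS1 at 6 months to 8.04 and 6.47 at 9 months (log2 1.02, SE 0.09, limma adjusted p = 0.00422). Pvalb, the calcium-binding protein of fast-spiking interneurons, rose from 37.6 and 31.1 to 44.1 and 43.5 (log2 0.36, SE 0.04, adjusted p = 0.034). Lrba (−0.29), Gm5900 (−1.10) and Phb (0.51) followed, not called (adjusted p = 0.077 each), and 1655 genes had an unadjusted p under 0.05, against 679.7 by chance. Pglyrp1 was called in each fit that left out a library, but not with region covariates (0.0844), while Pvalb was lost in 8 of 12 (adjusted p up to 0.108 without WT 1 of 9 months) and with region covariates (0.145). The count was 19 without APP/PS1 3 and 3 without WT 2 or APP/PS1 2 of 6 months, 9 without APP/PS1 1 and 4 without WT 2 or WT 3 of 9 months, and 1 without WT 1 or WT 3 of 6 months or WT 1 of 9 months.

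Lists with age were called at the preset correlation only. Cholesterol synthesis genes (15 of 16 higher, median log2 0.11), nuclear oxidative phosphorylation genes (21 of 22 higher, 0.09) and striatal genes (8 of 9 lower, −0.13) each had a camera adjusted p of 0.00012, and 0.461, 0.531 and 0.51 as adjusted p with an estimated correlation. Adjusted over the list alone 6 cholesterol genes rose and 2 striatal genes fell, and 0 over all genes. Endothelial genes were higher in 11 of 11 (0.10, 0.00134, and 0.247 with an estimated correlation), 3 of them adjusted over the list alone, with Ly6c1 at 21.5 and 19.5 FPKM at 6 months and 25.9 and 24.1 at 9 months. Reactive astrocyte genes were higher in 14 of 14 (0.15, 0.0102, and 0.51 with an estimated correlation) and thalamic genes in 10 of 10 (0.32, 0.0116, and 0.738 with an estimated correlation). Without WT 1 of 6 months these were not called (0.0727 and 0.118), nor without APP/PS1 3 of 9 months (0.0538, astrocyte) or APP/PS1 1 of 6 months (0.108, thalamus). Adjusted p-values of 0.0255 to 0.0302 were reached by glutamatergic (−0.06), disease-associated microglial (0.07), oligodendrocyte (0.09), pituitary (1.25), choroid plexus (0.51) and circadian genes (0.08), with 0.503 to 0.738 as adjusted p with an estimated correlation. Each of these 6 was lost in 4 to 7 of the 12 fits without a library, each of them without APP/PS1 1 of 6 months, with adjusted p up to 0.269 (choroid plexus without WT 1). Of the microglial members 5 were higher and 3 lower with age adjusted over the list alone. In the antigen presentation list, not called as a list and with median and mean below 0 and test above 0, Psmb8, an immunoproteasome gene, rose over the list alone from 1.03 and 1.18 to 1.39 and 1.68 FPKM (log2 0.40). Of the lists never called in any contrast, astrocyte, pan-neuronal, inhibitory neuron, oligodendrocyte precursor, mural cell, meningeal fibroblast, retina, cerebellum, hypothalamus, hippocampus, cerebral cortex and cytosolic ribosomal genes, the adjusted p ran from 0.054 to 0.999.

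The genotype effect differed between the ages for 1 gene, Hdac1, a histone deacetylase gene (5.95 ± 1.14 and 3.44 ± 0.348 FPKM in wild type and APP/PS1 at 6 months, 3.05 ± 0.0403 and 5.41 ± 0.217 at 9 months; log2 difference 1.52, SE 0.16, limma adjusted p = 0.0174). Its copy Gm10093 moved the other way by −1.64, and the sum of both differed by 0.42, so the value is uncertain. Without APP/PS1 2 of 6 months, WT 1 of 9 months or APP/PS1 3 of 9 months it was not called (0.0859, 0.0919 and 0.101). The call was also lost with region covariates (0.21), with the most abundant transcript (0.0582) and without APP/PS1 1 of 6 months and APP/PS1 1 of 9 months together (0.0648). Cthrc1 (2.09, adjusted p = 0.112), Egr1 (−0.78), Adora2a (0.66), Tcta (0.59) and Fdft1 (0.33, adjusted p = 0.186 each) were not called, and 1533 genes had an unadjusted p under 0.05, against 679.7 by chance. The counts without a library were 0 to 4, with 4 without WT 2 of 9 months, 3 without WT 2, WT 3 or APP/PS1 3 of 6 months or WT 3 of 9 months, and 2 without WT 1 of 6 months or APP/PS1 1 or 2 of 9 months. The effect on 10 lists also differed at the preset correlation. It was larger at 9 months for disease-associated microglial genes (median difference 0.30, camera adjusted p = 2.89e-05, and 0.159 with an estimated correlation), with Trem2, Ctsd and Lyz2 past the threshold over the list alone, and for cholesterol genes (0.24, 2.89e-05, and 0.275). For immediate early genes it was lower by −0.42 (5.7e-07, and 0.275 with an estimated correlation), with 8 members adjusted over the list alone, among them Egr1 and Arc.

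In the lncRNA table no gene was called between the genotypes at 6 or 9 months. Smaller changes could have been missed, since 43.3% of 1.5-fold changes of lncRNA genes were called in the simulation. Limma called 0 of 1367 genes at each age, with 100 and 57 genes at an unadjusted p under 0.05 (68.4 by chance), and no count tool could be run on FPKM. Gm25363 (2.05 ± 0.434 to 0.604 ± 0.413 FPKM, log2 −1.52, limma adjusted p = 0.0666), RP23-262I3.3 (2.54 ± 0.257 to 1.41 ± 0.101, −0.75, 0.0666) and Dubr (1.93 ± 0.0326 to 4.12 ± 1.06, 0.98, 0.0925) were closest at 6 months, and Gm22613 (1.495 ± 0.166 to 0.461 ± 0.222, −1.34, 0.124) at 9 months. The genotype effect differed between the ages for 0 genes (76 at an unadjusted p under 0.05), with the smallest adjusted p at 0.852. With age 5 lncRNAs were called, 2 higher and 3 lower at 9 months. ENSMUSG00000105843 rose from 1.75 ± 0.0820 and 1.36 ± 0.265 FPKM in wild type and APP/PS1 to 3.63 ± 0.233 and 2.28 ± 0.502 (log2 0.80, SE 0.11, adjusted p = 0.00915). RP23-336D20.8 rose from 0.272 ± 0.0589 and 1.74 ± 2.58 to 5.82 ± 2.70 and 5.81 ± 2.78 (log2 2.93, adjusted p = 0.0196), with 1 APP/PS1 library of 6 months within the range of 9 months. RP24-378G4.3 fell by 2.34 log2 (adjusted p = 0.0304), although APP/PS1 2 of 9 months lay at 3.16 FPKM within the 1.52 to 5.08 of 6 months. Falls of 0.58 and 0.54 were called for RP24-264B23.2 and RP23-116I16.1 (adjusted p = 0.0326 each). Files and labels used here give no function for these 5. With region covariates none of them was called (adjusted p from 0.0567 to 0.174, with ENSMUSG00000105843 at 0.14), and 1 other lncRNA was. Only ENSMUSG00000105843 was called in every fit without a library. The others were lost in 5, 8, 10 and 10 of the 12 fits, all 4 without WT 3 of 6 months, APP/PS1 2 of 6 months and WT 3 of 9 months, with adjusted p up to 0.0589, 0.0943, 0.107 and 0.117. The age count was 1 without WT 3 or APP/PS1 2 of 6 months or WT 3 of 9 months, 2 without WT 1 or APP/PS1 1 of 9 months and 3 without WT 2 of 6 months or WT 2, APP/PS1 2 or APP/PS1 3 of 9 months. At 6 months it was 1 for genotype without WT 3 or APP/PS1 1 and 3 without APP/PS1 3, at 9 months 1 without APP/PS1 1, and 1 for the difference between ages without APP/PS1 1 of 6 months.

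Circular RNAs, which form when a transcript's ends are joined by back-splicing, were tested by ID. At 6 months edgeR called 7 of 14872, 5 higher and 2 lower in APP/PS1, and 788 had an unadjusted p under 0.05 against 743.6 by chance (DESeq2 called 19). The groups did not overlap in 13.1% of circRNAs (10% by chance). The circRNA novel_circ_0045011 rose from 21.5 ± 1.87 to 194 ± 67.5 CPM (log2 3.18, SE 0.41, edgeR adjusted p = 0.00363), and novel_circ_0002726 from 50.5 ± 13.5 to 156 ± 52.4 (log2 1.65, adjusted p = 0.044). Another, mmu_circ_0000334, lay at 259 ± 32.7 in wild type and was listed at 0 in all 3 APP/PS1 libraries (edgeR adjusted p = 0.044). At 9 months it was read in all 3 APP/PS1 libraries (137, 106 and 99 reads) and listed at 0 in WT 3. The other 3 that were higher were listed at 0 in all 3 wild-type libraries and at means of 45.0 to 332.5 in APP/PS1 (adjusted p = 0.0409 each). For mmu_circ_0000011, chosen after its values were seen since its groups overlap, the log2 change was −2.49 (adjusted p = 0.044). With region covariates none of the 7 was called, novel_circ_0045011 included (log2 2.57, SE 0.58, adjusted p = 0.437), and 1 other circRNA was. The same novel_circ_0045011 kept its call in each fit that left out a library and, alone of the 7, with the default filter of edgeR (0.0443). The 5 others named by the rule were lost in 6 to 9 of the 12 fits, among them each without WT 1, 2 or 3 or APP/PS1 1 or 2 of 6 months, with adjusted p up to 0.303. The count ran from 1 without APP/PS1 2 of 6 months to 17 without WT 1 of 9 months. It was 4 without WT 1, 3 without WT 3, APP/PS1 1 or APP/PS1 3 of 6 months, 2 without WT 3, 4 without APP/PS1 1 and 11 without APP/PS1 3 of 9 months.

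At 9 months 1 circRNA was called by edgeR, novel_circ_0015795, which rose from 24.3 ± 7.09 to 154 ± 38.1 CPM (log2 2.57, SE 0.31, adjusted p = 0.00112), in 3 of 3 APP/PS1 libraries beyond wild type. At an unadjusted p under 0.05 there were 661 (743.6 by chance), the groups did not overlap in 10.5% (10% by chance), and DESeq2 called 4. The next, mmu_circ_0000453, was not called (log2 1.64, adjusted p = 0.212). At 6 months novel_circ_0015795 was lower in APP/PS1 (80.3 ± 6.18 in wild type and 23.3 ± 1.43 in APP/PS1), and its genotype effect differed between the ages (log2 difference 4.32, adjusted p = 0.000121). In all 6 circRNAs were called for that difference, 2 higher and 4 lower, with 890 at an unadjusted p under 0.05 and 17 by DESeq2. Among them novel_circ_0027638 lay at 645 ± 23.6 and 336 ± 24.8 at 6 months and 438 ± 135 and 630.0 ± 42.2 at 9 months (1.46, adjusted p = 0.034), and mmu_circ_0000598 at 424 ± 26.4 and 691 ± 64.6, then 670.1 ± 120 and 287 ± 148 (−1.94, adjusted p = 0.0432). Of these, novel_circ_0027638 was lost in 9 fits without a library (up to 0.112 without APP/PS1 3 of 6 months) and mmu_circ_0000598 in 10 (up to 0.126 without WT 3 of 6 months), while novel_circ_0015795 held in each and novel_circ_0045011 was lost without WT 3 of 6 months (0.0672). With region covariates none of the 6 was called for the difference (adjusted p = 0.0828 for novel_circ_0015795 and 0.674 to 0.94 for the others), while the call of novel_circ_0015795 at 9 months stayed (0.0314). With age edgeR called 1, novel_circ_0054039, listed at 0 in all 6 libraries of 6 months and in WT 3 of 9 months, and at 67.7 ± 58.7 and 92.8 ± 8.70 in the groups of 9 months (adjusted p = 0.0333), with 859 at an unadjusted p under 0.05 and 26 by DESeq2. It was lost without WT 1 or WT 3 of 6 months (0.0577 and 0.0573) or WT 2, APP/PS1 1 or APP/PS1 2 of 9 months (0.112, 0.0616 and 0.0506), and with region covariates (0.861). The age count was 0 without WT 2 of 9 months and reached 8 without WT 2, 6 without APP/PS1 1, 7 without APP/PS1 2 and 4 without APP/PS1 3 of 6 months, and 6 without WT 1, 3 without WT 3 and 10 without APP/PS1 3 of 9 months. For genotype at 9 months it was 4 without APP/PS1 2 of 6 months and 2, 3, 2 and 5 without WT 2, WT 3, APP/PS1 1 and APP/PS1 2 of 9 months. For the difference it was 11 without WT 3 of 9 months.

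No miRNA was called between the genotypes at 6 or 9 months. Smaller changes could have been missed, since 38.8% of 1.5-fold changes of miRNAs were called in the simulation. Without the filter some miRNAs were called at both ages, as given among the alternatives below. EdgeR called 0 of 560 at each age, with 32 and 30 at an unadjusted p under 0.05 (28 by chance), and DESeq2 called 0 and 2. The groups did not overlap in 8.39% and 11.1% of miRNAs (10% by chance). Closest at 6 months were mmu-miR-365-3p (49.4 ± 7.36 to 32.4 ± 4.85 CPM, log2 −0.63, edgeR adjusted p = 0.149) and mmu-miR-193b-3p (28.3 ± 3.20 to 18.3 ± 3.01, −0.65, 0.149), both lower in 3 of 3 libraries. The identical values of mmu-miR-467a-3p and mmu-miR-467d-3p (log2 −1.90, edgeR adjusted p = 0.149) cannot be told apart. At 9 months mmu-miR-29b-3p, which targets the Bace1 transcript, lay at 960.1 ± 538 in wild type and 325 ± 27.5 in APP/PS1 (log2 −1.53, adjusted p = 0.188 over all miRNAs and 0.00907 over the list alone). Only WT 1 and WT 2 of 9 months stood apart (1283.1 and 1258.1), with WT 3 at 339.0 and every library of 6 months at 284 to 369. The uncalled mmu-miR-376a-3p was likewise high in the same libraries (23.03 and 33.95, against 5.31 in WT 3). The list of miRNAs linked to BACE1 or APP was lower in 7 of 9 (median −0.11) and that of choroid plexus miRNAs in 4 of 4 (−0.47), at a camera adjusted p of 0.0157 each and an adjusted p of 0.525 with an estimated correlation. The BACE1 or APP list was lost without WT 1 (0.185) and the choroid plexus list without WT 3 (0.286) or APP/PS1 1 (0.0834) of 9 months. No list was called at 6 months (adjusted p from 0.906 to 0.925). The difference of the genotype effect between ages was called for 0 miRNAs by edgeR (35 at an unadjusted p under 0.05, smallest adjusted p 0.432) and 0 by DESeq2. Without WT 3 of 9 months 2 miRNAs were called for genotype at 9 months and 2 for that difference.

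With age 11 miRNAs were called, 10 lower and 1 higher at 9 months, and 61 had an unadjusted p under 0.05 against 28 by chance (DESeq2 called 16). The 10 that fell were members of the miR-200 family, kept low in most neurons and high in epithelia and olfactory tissue, and of the miR-183 cluster of sensory cells. Among them mmu-miR-200a-3p lay at 1819.9 ± 1419 CPM in wild type and 7783 ± 10388 in APP/PS1 at 6 months, and at 51.6 ± 12.1 and 74.9 ± 52.9 at 9 months (log2 −5.99, SE 1.11, edgeR adjusted p = 0.0258). Likewise mmu-miR-183-5p went from 822 ± 591 and 3378 ± 4617 to 41.6 ± 17.7 and 39.7 ± 6.06 (log2 −5.42, adjusted p = 0.0258), and mmu-miR-141-3p from 23.8 ± 20.995 and 93.6 ± 121 to 0.641 ± 0.253 and 2.09 ± 2.15 (−5.43, 0.0483). The spread at 6 months was large, with mean log2 levels of the 10 at 7.97, 5.23 and 8.31 in wild type and 10.99, 8.48 and 3.67 in APP/PS1, while the 6 libraries of 9 months lay at 3.30 to 4.58. The library APP/PS1 3 of 6 months was thus within the range of 9 months. Olfactory bulb markers of the long RNA libraries of the same names had mean log2 levels of 1.07, 0.14, 1.34, 2.74, 0.79 and −0.54 at 6 months and of −0.14 to −0.32 at 9 months. The miRNA that rose, mmu-miR-152-5p, went from 7.13 ± 0.712 and 8.88 ± 1.79 to 13.6 ± 2.89 and 13.2 ± 2.995 (log2 0.72, adjusted p = 0.0483). Each call was lost in 8 to 11 of the 12 fits without a library, all of them without WT 1 or WT 3 of 6 months or any library of 9 months, with adjusted p up to 0.171. The count was 0 without those 8 libraries except WT 3 of 9 months (2), and 16 without APP/PS1 3 and 7 without APP/PS1 2 of 6 months, and with region covariates none of the 11 was called (1 other miRNA was). The list of retina miRNAs, which holds 3 miRNAs of the miR-183 cluster, was lower (median −4.86, adjusted p = 0.000417, and 0.194 with an estimated correlation), and inflammation-linked miRNAs were higher in 9 of 9 (0.14, 0.0172, and 0.189 with an estimated correlation), a call lost without APP/PS1 2 of 6 months (0.081) and with region covariates (0.353). Neuron-enriched, oligodendrocyte, blood-cell, endothelial and activity-linked miRNAs were not called in any contrast (adjusted p from 0.121 to 0.942).

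**Figure D3:**
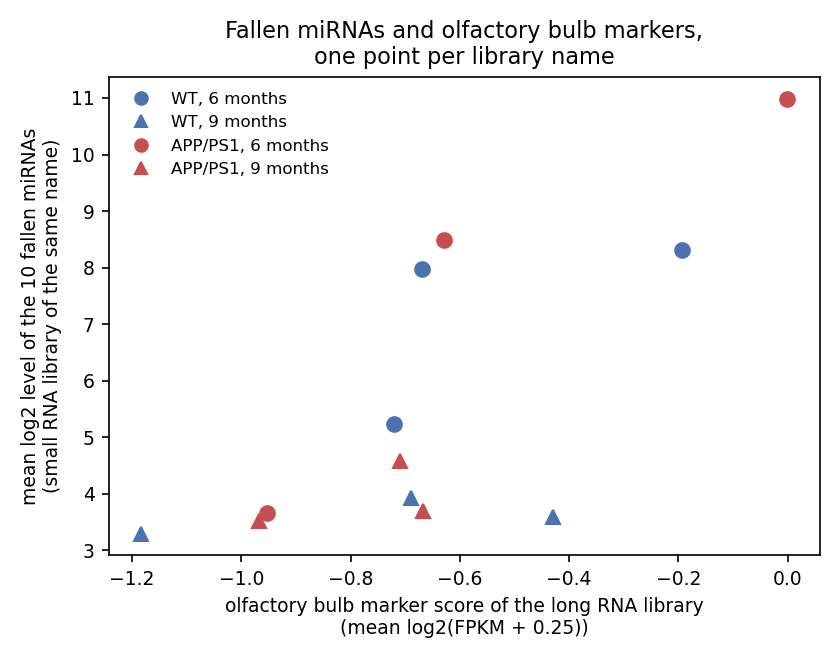
Mean log2 level of the 10 miRNAs that fell with age against the mean log2(FPKM + 0.25) of 5 olfactory bulb markers in the long RNA library of the same name, with circles for 6 months and triangles for 9 months. Over the 6 libraries of 6 months Spearman rho is 0.943, and over those of 9 months 0.429.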

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

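The tests of tissue markers and region covariates, of circRNA zeros and of the microglial lists in this part were chosen after seeing the results they address. The results in this paragraph stood out because a test of the difference found a genotype effect at 9 months unlike that at 6 months. Hdac1 differed by 1.52 log2 (limma adjusted p = 0.0174), with its likely copy Gm10093 going the other way by −1.64 and the sum of both between 5.97 and 7.91 FPKM in all libraries. Among circRNAs (edgeR), novel_circ_0015795 differed by 4.32 (adjusted p = 0.000121), novel_circ_0027638 by 1.46 (0.034), novel_circ_0045011 by −3.43 (0.0112) and mmu_circ_0000598 by −1.94 (0.0432). The fitted differences of novel_circ_0015639 (−11.16) and novel_circ_0015649 (−13.38, adjusted p = 0.00271 each) rest on groups listed at 0 and are no bounds. With region covariates none of these 7 was called. Hdac1 went to 1.38 (SE 0.21, before 0.16, limma adjusted p = 0.21), mostly through a wider error. The difference of novel_circ_0015795 was 4.28 (SE implied by F 0.65, before 0.45, edgeR adjusted p = 0.0828), so it changed little while F fell. The 5 others had adjusted p from 0.674 to 0.94. Among lists (camera, median log2 difference), disease-associated microglial genes stood at 0.30 (adjusted p = 2.89e-05), complement at 0.32 (0.00214), cholesterol synthesis at 0.24 (2.89e-05), striatum at 0.35 (5.7e-07) and immediate early genes at −0.42 (5.7e-07). Choroid plexus genes stood at −1.66 (3.87e-07), ependymal cilia at −0.58 (0.000679), thalamus at −0.40 (0.0369), mitochondrially encoded genes at −0.33 (0.00146) and protein folding stress genes at −0.24 (0.00214). With an estimated correlation none of the 10 lists was called (adjusted p from 0.159 to 0.938). Leaving out WT 1 of 6 months ended the calls of thalamus (0.896) and protein folding (0.101), and leaving out APP/PS1 3 of 6 months that of mitochondrially encoded genes (0.0684). Regroupings of the libraries gave as many list calls in 38 of 100 splits. Such regroupings can keep the real genotypes at a single age, which turns a genotype effect into a difference between ages. This set of differences was thus not shown to exceed chance, and that share cannot settle it.

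The fall of the miR-200 and miR-183 families with age could come from unequal amounts of olfactory bulb in the samples, from retina carried over, or from age. In the 6 libraries of 6 months the mean level of the 10 miRNAs followed 5 olfactory bulb markers not looked at before. Spearman rho was 0.943 (exact permutation p = 0.0167, Benjamini-Hochberg 0.05 over 9 relations). Pearson r was 0.864 (exact permutation p = 0.0236, 0.0531 after adjustment), and 0.907 without the 2 farthest libraries. This goes with unequal olfactory bulb tissue among these libraries, but weakly, as only 2 of the 5 markers passed the filter of 0.5 FPKM. The other 7 olfactory bulb markers, 6 of them past that filter, had already been looked at in these data. They had r 0.961 over the same libraries (exact permutation p = 0.00556), which is thus no independent support. Over the libraries of 9 months these 7 went the other way (r −0.638, exact permutation p = 0.151). Retina markers did not follow the miRNAs (rho −0.6, exact permutation p = 0.242). Their r was −0.295 (exact permutation p = 0.6), and −0.939 without the 2 farthest libraries. Only 3 of 10 passed that filter, and their score was −0.27 to 0.009 in every library, so a small amount of retina cannot be judged from them. With the 5 olfactory bulb markers alone as covariate 0 miRNAs were called, as the folds shrank (mmu-miR-200a-3p from −5.99, SE 1.11, to −4.18, SE 0.97, edgeR adjusted p = 0.124), but they shrank about as much with the choroid plexus score alone (−4.39, SE 1.01, adjusted p = 0.123). How much of the fall between ages comes from olfactory bulb, retina or age itself stays open, and small and long RNA libraries were matched by name only.

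A set of 70 circRNAs was listed at 0 in some libraries and well read in all others. Of them 3 were called, mmu_circ_0000334 and novel_circ_0010579 for genotype at 6 months and novel_circ_0054039 with age. What makes the zeros may also have made these calls. The zeros could come from count sampling, from reads listed under another ID, or from genotype and age. Sampling is unlikely, since 20 simulations gave at most 0 such circRNAs, and the reads foreseen where 0 was listed had a median of 46.5. A partner ID holding the missing reads was found for 5 of the 70 (7.14%). Among the 39 whose own variation allowed it these were 5 (12.8%), against a median of 6 and at most 10 of the 39 in shuffles. This speaks against a single other ID as the main source. Libraries of the same group shared presence or absence in 74.0% of pairs (other groupings 67.4% to 71.7%, one-sided permutation p = 0.0018 over 10000 groupings), which is consistent with a part set by group. None was at 0 in exactly the libraries of a genotype, age or group, and libraries with more reads had fewer zeros (6 to 19 per library; r −0.878, permutation p = 0.00131; rho −0.774, permutation p = 0.00447; r −0.602 without the 2 farthest).

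The higher disease-associated microglial genes at 9 months could reflect more microglia of unchanged make-up, unequal tissue pieces, or a changed microglial state. Their median exceeded that of homeostatic genes by 0.205 (0.455 against 0.25, permutation p = 0.211 over genes, which are not independent), so more microglia stays open. With olfactory bulb and choroid plexus scores as covariates the median was 0.513, with 18 of 19 genes higher, which speaks against these tissue pieces as the cause. The homeostatic median under the same covariates was 0.177, with 10 of 12 genes higher, a wider gap that was not tested. A changed state was not separated from cell number by any test here.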

How the results depend on the processing

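The alternatives with the most abundant transcript, region covariates, the pair of libraries left out and circRNAs left out were tests chosen after seeing the data. So were the pseudocounts and scaling for lncRNA and every alternative for miRNA lists. App, Prnp and Cst7 kept direction and call in every genotype comparison. Without each library in turn, calls ran from 4 to 17 (mRNA, genotype at 6 months), 5 to 14 (9 months), 8 to 16 (both ages), 1 to 19 (age) and 0 to 4 (difference between ages), for lncRNA 0 to 3, 0 to 1, 1 to 6 (age) and 0 to 1 (difference), for circRNA 1 to 17, 1 to 5, 0 to 10 (age) and 4 to 11 (difference), and for miRNA 0 to 0, 0 to 2, 0 to 16 (age) and 0 to 2 (difference). List calls ran from 55 to 69 (mRNA, 64 in the model used) and 3 to 5 (miRNA, 4). With an estimated correlation 5 mRNA lists and 0 miRNA lists were called. Without the pair of libraries high in olfactory bulb or pituitary markers, calls were mRNA 11 at 6 months, 8 for age and 0 for the difference, lncRNA 1 at 6 months, 1 at 9 months, 3 for age and 1 for the difference, circRNA 3 at 6 months, 2 at 9 months and 5 for age, and miRNA 0 for age. With region covariates they were mRNA 7 at 9 months and 0 for age, lncRNA 1 for age, circRNA 1 at 6 months and 0 for the difference, and miRNA 1 for age (0 with the olfactory bulb score alone, 0 with the 5 markers not looked at before alone and 1 with the choroid plexus score alone). Of these, 6 of the 7 mRNA calls at 9 months and none of the 1 each for lncRNA, circRNA and miRNA were calls of the model used. DESeq2 called circRNAs 19 at 6 months, 4 at 9 months, 26 for age and 17 for the difference, and miRNAs 2 at 9 months. The default filter of edgeR gave circRNAs 1 at 6 months, 0 for age and 3 for the difference, and a fit of 2 groups gave 23 at 6 months and 2 at 9 months. Without all-or-none circRNAs 9 were called for age. No filter gave miRNAs 27 at 6 months, 14 at 9 months, 28 for age and 15 for the difference, and mRNA 1 for age. A pseudocount of 0.05 gave 10 genes over both ages, the most abundant transcript 1 for age and 0 for the difference, and median-of-ratios scaling 2 lncRNAs for age. Library numbers do not pair the samples (same-number pairs with r over 0.1 were 0, 4, 2 and 1 of 18 for circRNA, lncRNA, miRNA and mRNA). With the library number as a block, the age calls were mRNA 1, lncRNA 2, circRNA 10 and miRNA 0, and 10 circRNAs for the difference. Directions turned for Gpr34 over both ages (−0.0772), Apoe (0.308) and Rgs9 (0.0453) with age under the most abundant transcript, and App for the difference (−0.0288 to 0.0115 without each library, above 0 without APP/PS1 3 of 6 months or APP/PS1 2 of 9 months), and with region covariates for the choroid plexus list with age (adjusted p = 0.336, a test without meaning, as that score holds its own members) and the thalamus list for the difference (0.392). The cause was not tested for these shifts. Alternatives for lncRNA counts (DESeq2, RLE and the authors' depth) and the circRNA share of total depth were not run, as the files hold no such counts or depth. The circRNA medians of 7.08 reads limit detection.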

Other observations

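Y-linked genes, which mark male tissue, were read in every long RNA library, with Ddx3y at 26.3 to 31.6 FPKM, Eif2s3y at 16.9 to 23.8, Kdm5d at 5.76 to 7.72 and Uty at 12.4 to 14.9. Olfactory genes varied between libraries of the same group. Cdhr1, Doc2g and Omp, markers of the olfactory bulb and nerve, lay at 14.6, 14.4 and 9.70 FPKM in APP/PS1 1 of 6 months and at 1.63, 0.72 and 0.37 in APP/PS1 3 of 6 months. Ttr, a choroid plexus gene, lay at 91.6 ± 152 and 223 ± 115 FPKM in wild type and APP/PS1 at 6 months and at 309 ± 20.7 and 147 ± 110.3 at 9 months, and was not called.

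The tests in this paragraph compared each count of calls with other groupings of the same libraries, the real grouping included. For mRNA over both ages 1 of 100 splits gave as many as the 16 calls (highest other 7), for age 16 of 100 as many as 2 (highest other 3) and for the difference between ages 41 of 100 as many as 1 (highest other 13). For lncRNA 1 of 100 gave as many as the 5 for age (highest other 2) and 100 of 100 as many as 0 for the difference (2). For circRNA 3 of 40 gave as many as 1 for age (highest other 6) and 1 of 40 as many as 6 for the difference (4). For miRNA 2 of 100 gave as many as 11 for age (highest other 12) and 100 of 100 as many as 0 for the difference (3). For mRNA lists 5 of 100 gave as many as 15 over both ages (highest other 18, median 8). For age 7 of 100 gave as many as 12 (16, median 7) and for the difference 38 of 100 as many as 10 (19, median 8). Other groupings thus also gave many list calls at the preset correlation. They can keep a part of the real contrast, so their medians are no rate of calls without a change. For miRNA lists 10 of 100 gave as many as 2 for age (3) and 100 of 100 as many as 0 for the difference (2). The mRNA count for the difference between ages was often reached by other groupings. As said above, these can carry a genotype effect into that difference, so the shares of 41 and 38 of 100 cannot decide it. The counts for age in mRNA and circRNA lay above the median of other groupings (0 for both). The share of splits that reached them was still not under 0.05.

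For genotype at a given age only 10 splits exist, too few for a share under 0.05. The other splits called a median of 6 mRNA lists at 6 months and of 8 at 9 months. Each of them puts unequal numbers of the genotypes on a side, so a part of the genotype contrast stays in it. At 6 months as many calls came in 1 of 10 splits for mRNA (6, highest other 3), 10 for lncRNA (0, 0), 1 for circRNA (7, 1), 10 for miRNA (0, 3), 3 for mRNA lists (9, 10) and 10 for miRNA lists (0, 2). At 9 months they came in 1 of 10 for mRNA (13, highest other 1), 10 for lncRNA (0, 0), 4 for circRNA (1, 2), 10 for miRNA (0, 0), 1 for mRNA lists (18, 12) and 1 for miRNA lists (2, 1).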
